A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

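The data were 4 arrays of chromatin immunoprecipitation (ChIP) of the recombination protein Rad52 from fission yeast, Schizosaccharomyces pombe. Per the labels, 2 arrays came from cdc25-22 rif1Δ cells and 2 from cdc25-22 rif1Δ rad3Δ cells. The cdc25-22 allele stops cells before mitosis at high temperature, and the labels give a block of 4 h at 36.5 °C, release at 25 °C and treatment with 6 mM hydroxyurea, which slows replication forks by lowering nucleotide pools. Strains and replicate numbers were taken from the labels, and nothing in them says that replicates were separate cultures, so p-values measure the spread between these arrays, which may be technical.

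Per the file headers, the arrays were 2-colour Agilent tiling arrays with 60-nt probes at a median spacing of 265 bp, read with Agilent Feature Extraction 10.7.3.1. Per the labels, the input was labelled with Cy5 and the ChIP sample with Cy3 on all arrays. The deposited intensity values used were the processed signals, which per the file headers are background-subtracted and scaled by a linear dye factor for each channel. Median spot and background intensity, also deposited, served for alternatives. The deposited log10 ratio equals the log10 of Cy5 over Cy3 processed signal and was used only to check the direction. The authors' value table holds a linear ratio, equal to Cy3 over Cy5 processed signal, without centring. Its column medians were 0.985, 1.01, 0.968 and 1.01. No mean spot signal was used here, so the normexp alternative (offset 50) and the alternative without dye normalization started from median spot signals.

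The log2 of ChIP over input was computed per probe, and each array was centred on its median over nuclear probes, with no loess or quantile step. Probes that Feature Extraction called outliers on any array, 97 in all, and 2513 control spots were left out, which left 42548 probes. Between 96.2% and 99.8% of probes were well above background in each channel. Probe values were averaged in bins of 1 kb with at least 2 probes, which gave 12047 bins. The number of arrays limits the precision.

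Coordinates are those of the array design, whose header names a Feb2002 NCBI build. Probe brightness followed the GC content of the given reference genome at an offset of 0 on chromosomes II and III and on chromosome I up to its centromere. It did not on chromosome I beyond 3753000 bp, where the best match lay 6130 bp away. Coordinates were not converted, so 14.2% of probes, on that arm, carry no gene names, and 16 of the 98 genes in the fixed lists were not analysed here. List genes were matched by symbol first and then by synonym. In a first run a synonym could go before another gene's own symbol, which put wrong genes in the stress and repair classes, and the gene test matched symbols only. This was corrected after the results were seen; no class call of the report changed, but class medians then gave 5 class differences instead of none, and normexp fewer.

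Bins, genes and feature classes were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 4 arrays, with a mean for each strain. Each mean was tested against 0 and the strains against each other, with Benjamini-Hochberg adjustment at 0.05, and all adjusted p-values given are limma's unless another test is named. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333. Classes were also set against 10000 circular rotations of their intervals along the annotated probes, two-sided, for which 1e-04 is the smallest p possible, and tested with camera over bins. Camera was run with a preset correlation between bins of 0.01 and with an estimated one. With the estimated one, its p-values rest on the 2 residual degrees of freedom, so few classes could pass.

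In simulated data with 200 changed bins among 12047, averaged over 20 draws, the test between strains recovered 96.4% of changes of 1 on the log2 scale and 3.58% of changes of 0.5. Of its calls, 7.02% were false at a change of 1 and 25.1% at 0.5. The test of enrichment recovered 53.2% of bins raised by 0.5 and all raised by 1. The simulated data had fewer changed bins than were called on these arrays. Their noise was normal, independent between bins and of the same spread in both strains. These rates therefore need not hold for the arrays. Rotations of 3 classes placed at random gave p below 0.05 in 4.5% to 6.5% of 200 placements. Each placement is itself a rotation, so shares near these follow from the design. They check the calculation only, not whether rotations suit these classes.

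Regions are runs of called bins of the same sign, joined over gaps of 1 bin. Before the data were examined, the rule for named regions was set as the 10 with the highest peak bin in each strain, at 1.5-fold or more, and the 10 with the largest change in each direction, among bins whose arrays do not overlap between strains. A set of fixed loci and up to 4 members of each class were also to be named. Bins inside rif1 and rad3 hold no DNA in the strains that lack these genes and were left out of naming and of the gene test. The mat1 genes hold no probe, so, once this was seen, the mat1 region was taken with 2 kb on either side.

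The class written beforehand as silent mating-type region was given limits that begin at mat1. After the data showed the tallest peak beside mat1, a narrower version, from the annotated mat2-mat3 features, took their place for a time. The first limits were then restored for the values in the report and the narrower version made an alternative, and both sets of values are given with the alternatives. Alternatives changed the start values, centring, scale, intensity and A+T corrections, probe filter, bin size, prior, blocks and arrays used. The turned sign was not run, since the labels and the authors' table give the same direction. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with 1.17.8 of the R package data.table.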

Results

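Rad52 ChIP signal was mapped on tiling arrays in cells without Rif1 and in cells without Rif1 and the checkpoint kinase Rad3. Rif1 is a protein that limits the firing of replication origins. Each strain had 2 arrays, each with its own input channel. Median ChIP signals were 390 to 1115 and median input signals 573 to 2145, over backgrounds of 38 to 108. Both lowest medians, 390 and 573, were those of rif1Δ rad3Δ replicate 2. Per the file headers, its derivative log ratio spread, a measure of noise between probes, was 0.452, against 0.311 to 0.322 on the other arrays. It alone was read with a ChIP protocol of Feature Extraction, and the others with a CGH protocol. Profiles over 12047 bins of 1 kb correlated at r = 0.629 between the rif1Δ arrays and 0.844 between the rif1Δ rad3Δ arrays, and at 0.293 to 0.427 between arrays of different strains. These are correlations across bins, which are not independent replicates.

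The deleted genes were examined first. Probes in rif1 (chromosome I, 2766273 to 2770704) lay at 1.18% to 2.5% of the array median in the ChIP channel and 0.867% to 3.48% in the input channel of all 4 arrays. Probes in rad3 (chromosome II, 904184 to 913629) lay at 63.2% and 79.6% of the ChIP median on the rif1Δ arrays, and at 6.1% and 1.23% on the rif1Δ rad3Δ arrays. The input channel of the rif1Δ rad3Δ arrays held rad3 at 1.82% and 0.972% of its median, and rif1 at 1.84% and 0.867%. The labels give that input as cdc25-22 without either deletion, and these probes go against that label. The comparison genes cdc25 and rad52 were at 43.3% to 96.9% of the input median on all arrays. Of 15 bins in the deleted genes, 8 were called enriched in rif1Δ rad3Δ and 5 as different between strains, and none of these is read as Rad52, though the counts of bins given for the strains and their difference include them.

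In rif1Δ cells, the Rad52 ChIP signal was highest in a set of tall peaks. No ChIP without Rad52 was measured here, so these peaks cannot be told apart from enrichment without the protein. The tallest stood over rga7, next to the mating-type locus mat1, with its peak bin at chromosome II, 2112000 to 2112999, and a log2 ChIP over input of 4.06 ± 0.20 (SD, n = 2), or 16.7-fold. The cysteine transporter gene SPCPB1C11.03 on chromosome III reached 3.21 ± 0.63 (SD, n = 2). The septum glucanase gene eng1, which acts in cell separation, reached 3.02 ± 0.27 (SD, n = 2) in a region from 994000 to 1003999 on chromosome I. Peaks also stood over SPBPB7E8.01 at 2.77 ± 0.028, the cell wall glucosidase gene exg1 at 2.08 ± 0.23 and the homocysteine synthase gene met17 at 1.79 ± 0.099 (SD, n = 2 each). The other 4 of the 10 highest regions lay on the arm of chromosome I without names here, the tallest at 5238000 to 5238999 with 6.8-fold.

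In all, 520 bins were enriched and 117 depleted in rif1Δ (limma, adjusted p below the threshold). Adjusted p was 1.26e-06 at rga7, 4.93e-05 at SPCPB1C11.03 and 7.10e-06 at eng1. At 1.5-fold or more, the enriched bins formed 192 regions. The enriched count fell to 285 without replicate 1 of rif1Δ and to 208 without replicate 2, and the depleted count to 35 and 11. The depleted count was 8 with arrays centred on the mode, 220 with loess and 1028 with the replicate block.

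In rif1Δ rad3Δ cells, the pattern was denser. The rga7 peak was again the tallest, at 3.52 ± 0.24 (SD, n = 2), or 11.5-fold. It was followed by the centromere of chromosome II beside a valine tRNA gene (2.48 ± 0.16), a bin with a long terminal repeat at 1575000 on chromosome III (2.35 ± 0.46), the transcription factor gene SPBC56F2.05C (2.34 ± 0.23) and a bin beside SPCC18B5.02C and wee1 (2.30 ± 0.0080; SD, n = 2 each). A bin with a glutamate tRNA gene at the centromere of chromosome III reached 2.28 ± 0.010, a glutamine tRNA gene 2.20 ± 0.16 and the spindle checkpoint gene mad1 2.06 ± 0.11 (SD, n = 2 each). In rif1Δ the valine, glutamate and glutamine tRNA bins already stood at 1.76, 1.56 and 1.93. The glutamine bin lies inside the rif1Δ region of SPCPB1C11.03, and its difference between strains did not pass (limma adjusted p = 0.273). The bin beside SPBP23A10.11C was at 2.09 ± 0.32 and SPAC343.21 at 2.08 ± 0.36 (SD, n = 2 each).

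Here 2949 bins were enriched and 2935 depleted in limma, and the enriched bins of 1.5-fold or more formed 684 regions. Adjusted p was 7.89e-06 at rga7 and 3.65e-05 at mad1. The SD over bins was 0.511 and 0.532 on the rif1Δ rad3Δ arrays against 0.318 and 0.343 on the rif1Δ arrays. With every array scaled to one spread, 1892 bins were enriched in rif1Δ rad3Δ and 946 in rif1Δ, and 1773 were depleted in rif1Δ rad3Δ and 541 in rif1Δ. Without replicate 2 of rif1Δ rad3Δ, 1604 bins were depleted there.

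**Figure D1:**
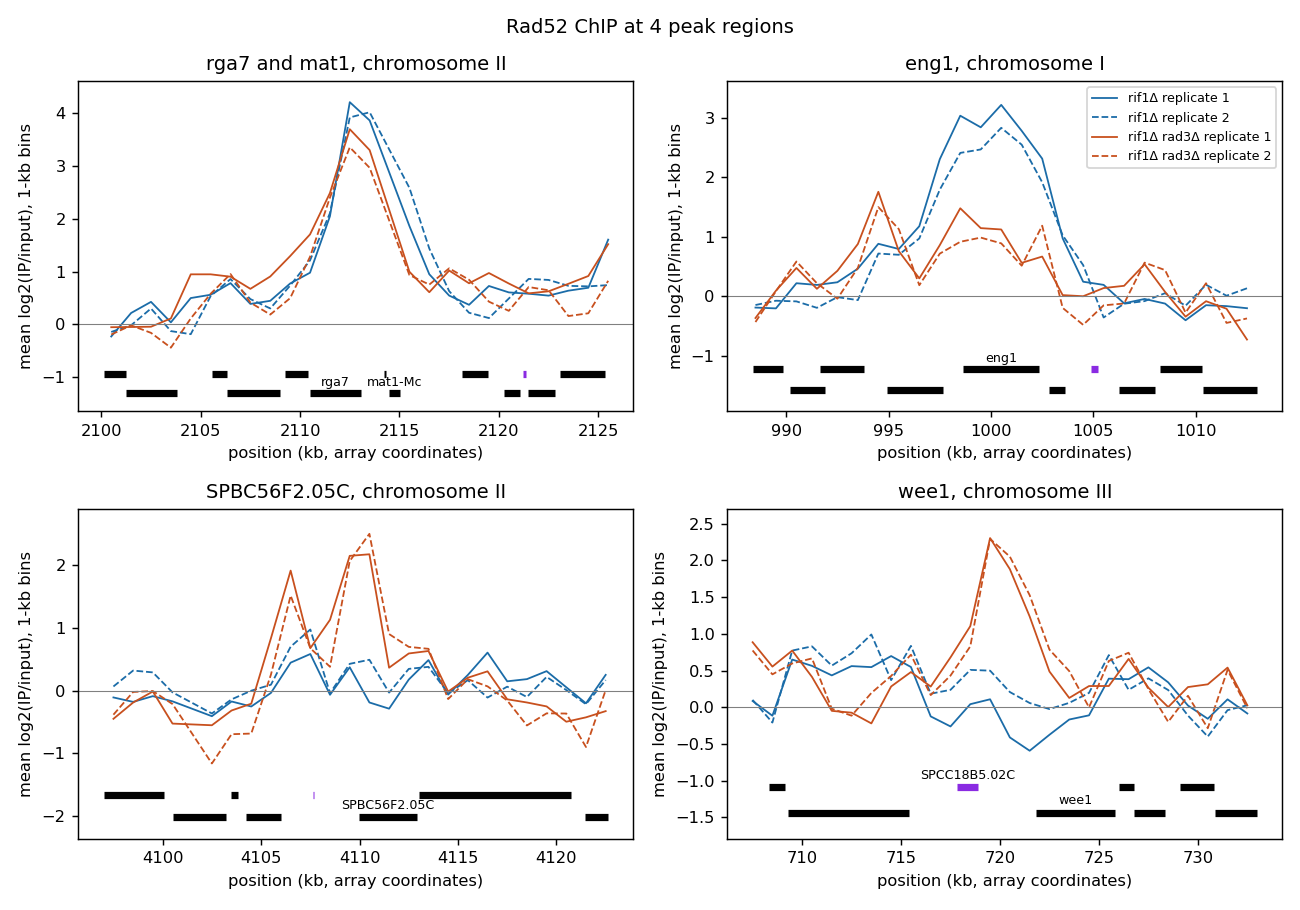
Mean log2 ChIP over input in 1-kb bins (vertical axes) against position in kb (horizontal axes) at 4 regions, with a line for each array, blue for rif1Δ and orange for rif1Δ rad3Δ, solid for replicate 1 and dashed for replicate 2; bars below are genes, black for protein-coding and purple for other kinds. The rga7 peak stands in both strains, the eng1 peak is taller in rif1Δ (3.02 against 1.01), and the peaks at SPBC56F2.05C and beside wee1 stand in rif1Δ rad3Δ.

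The comparison of the strains asks whether Rad52 lies elsewhere once Rad3 is also missing. The Rad52 ChIP signal was lower in rif1Δ rad3Δ over the cysteine transporter gene SPCPB1C11.03, with a log2 change of -2.18 ± 0.29 (SE), over eng1, with -2.12 ± 0.16, and over the alcohol dehydrogenase gene adh1, with -1.60 ± 0.22 (SE, n = 2 arrays per strain each). It was higher over SPBC56F2.05C by 2.18 ± 0.24, beside wee1, the kinase gene that holds cells back from mitosis, by 2.07 ± 0.22, and at the bin nearest SPCC74.04, a transporter gene, by 1.73 ± 0.17 (SE, n = 2 arrays per strain each). Limma's adjusted p was 0.00561 at SPCPB1C11.03, 0.00462 at eng1 and SPCC74.04, 0.00612 at adh1, and 0.00486 at SPBC56F2.05C and beside wee1. At rga7 the difference of -0.54 ± 0.19 (SE) did not pass, with an adjusted p of 0.0743. The mat1 region, given below with the fixed loci, covers part of this same peak, so they are not separate results.

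Other regions with the largest falls were SPBPB7E8.01 (-1.66), the calcium transporter gene cta3 (-1.52) and 3 regions of the unnamed arm. In rga2 the level went from -0.12 ± 0.012 to -1.77 ± 0.18 and in the glucosidase gene adg3 from 0.33 ± 0.058 to -1.15 ± 0.32 (SD, n = 2 each), so there the change was a loss below the array median, not of a rif1Δ peak. The rga2 region spanned 25 bins. Other regions with the largest rises were at wtf25 (1.86), near abo2 (1.77), beside a long terminal repeat at 1804000 on chromosome II (1.77), at sws2 (1.68) and 3 on the unnamed arm. At wtf25, abo2, sws2 and adg3 some probes of the bin were not well above background on every array.

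In all, 1238 bins were higher and 983 lower in rif1Δ rad3Δ in limma, of 12047. The split was 582 higher and 771 lower with normexp, and 612 and 747 with arrays centred on the mode. With arrays scaled to one spread, 457 bins differed. Without any 1 array the count was 1309 (rif1Δ replicate 1), 1039 (rif1Δ replicate 2), 1239 (rif1Δ rad3Δ replicate 1) and 1285 (rif1Δ rad3Δ replicate 2). One slide held replicate 1 of both strains, and over all bins the difference within that slide correlated with that of the replicate 2 arrays at r = 0.764.

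Of the enriched bins of rif1Δ, 332, or 63.8%, were also enriched in rif1Δ rad3Δ. The share was 40.8% without replicate 2 of rif1Δ rad3Δ and 41.8% with arrays scaled to one spread. Independent lists would share 127.3 bins. Rotating one list along the genome gave 276 shared bins at most (10000 rotations, permutation p = 1e-04, the smallest they can give). Both lists come from one fit in which the strains share each bin's spread. Neither comparison keeps this link, so part of the excess may come from it.

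Among the loci fixed beforehand, the mat1 region, where mating-type switching starts from an imprint, fell from 2.95 to 2.14 (difference -0.80 ± 0.15 SE, limma adjusted p = 0.0222). Its margins were set only once the mat1 genes were seen to hold no probe, and they take in part of the rga7 peak. The leucine synthesis gene leu1 fell from 0.78 to 0.18 (-0.60 ± 0.14 SE, adjusted p = 0.0350) and the adenine synthesis gene ade6 from -0.17 to -0.82 (-0.65 ± 0.12 SE, adjusted p = 0.0233). The single centromeres were not among the fixed loci, though their class was set beforehand. The centromere of chromosome III rose from 1.55 to 2.15 (0.61 ± 0.12 SE, adjusted p = 0.0237), with the sign turned to -0.26 when arrays were scaled to one spread. With the A+T trend removed, cen3 (0.16), ade6 (-0.44) and leu1 (-0.36) did not pass. Leaving out single arrays also undid the calls at cen3 (0.55 and 0.66 without rif1Δ replicates 1 and 2), ade6 (-0.63 and -0.67 without the same), leu1 (-0.44 without rif1Δ replicate 1) and the mat1 region (-0.65 without rif1Δ replicate 2). The centromeres of chromosomes I and II went from 1.07 to 1.33 and from 1.25 to 1.65, with adjusted p of 0.187 and 0.111. The 6 probes of the centromere of chromosome I lie on the part whose coordinates were not matched to the reference, so their place is less certain. They are among the 42 probes of the centromere class mean, while its rotations used the 36 annotated probes. The gene rad52 was at 0.49 and 0.27, ura4, beside the origin ars3002, at 0.29 and -0.10, hus5, beside ars1, at 0.15 and -0.092, cdc25 at 0.17 and 0.040, and the subtelomeric helicase gene tlh1 at 0.21 and -0.70, with no difference that passed. The gene tlh2 was not analysed here.

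In rif1Δ, several gene classes had a log2 ChIP over input above the array median, which is set to 0. Core histone genes stood at 0.80 ± 0.33, glycolytic and fermentation genes at 0.68 ± 0.052, 5S rRNA genes at 0.65 ± 0.011, tRNA genes at 0.57 ± 0.071 and snRNA and snoRNA genes at 0.49 ± 0.061, as class means of log2 ChIP over input (SD, n = 2 each). Centromeres were at 1.27 ± 0.23, the mating-type region at 0.79 ± 0.0057, cytosolic ribosomal protein genes at 0.32 ± 0.095, convergent intergenic regions at 0.23 ± 0.0044, stress and heat-shock genes at 0.19 ± 0.032 and G1/S (MBF) targets at 0.19 ± 0.045 (SD, n = 2 each). These 11 of 18 classes passed in limma and against rotations, but camera with an estimated correlation called 0 of them, with a lowest adjusted p of 0.205. With 2 residual degrees of freedom, that setting cannot show whether correlation between bins undoes these classes. For convergent regions the estimated correlation was 0.00263, below the preset 0.01, yet camera's unadjusted p went from 5.57e-06 to 0.0205. Without either rif1Δ array, G1/S targets, convergent regions and stress genes no longer passed, nor did ribosomal protein genes without replicate 2, which left 8 and 7 classes. Members with high levels in rif1Δ were the hexose transporter gene ght5 (1.55), the histone gene htb1 (1.30), the transcription regulator gene tos4 (1.24), the pyruvate decarboxylase gene pdc101 (1.13) and the glyceraldehyde phosphate dehydrogenase gene tdh1 (1.12).

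In rif1Δ rad3Δ, A+T-rich islands, the sequence feature of fission yeast origins, stood at 0.63 ± 0.22 against 0.093 ± 0.15 in rif1Δ, and divergent intergenic regions at 0.31 ± 0.13 against -0.028 ± 0.060 (SD, n = 2 each). The ends of chromosome III were at 0.71 ± 0.14, centromeres at 1.69 ± 0.040, 5S rRNA genes at 0.66 ± 0.19, tRNA genes at 0.42 ± 0.15 and coding genes longer than 5 kb at -0.22 ± 0.0087 (SD, n = 2 each). Glycolytic and fermentation genes stood at 0.060 ± 0.21, histone genes at 0.20 ± 0.11 and ribosomal protein genes at -0.038 ± 0.051 (SD, n = 2 each), none past the threshold. In limma, 9 classes were above and 2 below 0, the second of these recombination and repair genes at -0.26 ± 0.086 (SD, n = 2), but camera with an estimated correlation called 0, with a lowest adjusted p of 0.114. With the A+T trend removed, 6 classes were above 0, and the difference of A+T-rich islands between the strains was largely gone, as given below. A+T content defines these islands, so the removal takes out signal there whatever its source. For this class the setting cannot tell an effect of base content from Rad52 at the islands.

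Of the class differences, 0 of 18 passed in limma and 9 had an unadjusted p below 0.05, with a lowest adjusted p of 0.0730. Against rotations 9 passed, a test that compares places on the genome and not arrays. In limma 11 passed with normexp, 6 each with loess, the A+T trend removed and the replicate block, and 5 with class medians. The glycolytic class changed by -0.62 ± 0.13 (SE) and A+T-rich islands by 0.53 ± 0.15 (SE), both with an adjusted p of 0.0730. With the A+T trend removed they were -0.34 and 0.030. The second value decides nothing about the islands, since A+T content defines them. With arrays scaled to one spread the glycolytic class passed, at -0.82 (adjusted p = 0.0347). Camera called 11 differences with a preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.101.

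In the gene lists fixed beforehand, 9 of 13 glycolytic genes were lower in rif1Δ rad3Δ over all 4361 genes tested (10 adjusted over the list alone), among them adh1 (-1.28 ± 0.24 SE), ght5 (-0.82 ± 0.19), fba1 (-0.88 ± 0.22) and eno101 (-0.74 ± 0.19; SE each). Of 17 G1/S targets, 2 were lower, cdt1 (-0.85 ± 0.11) and tos4 (-0.92 ± 0.15), with 2 adjusted over the list alone. Of 21 recombination and repair genes, 2 were higher, among them nbs1 (0.82 ± 0.13), and 5 lower, among them mus81 (-0.53 ± 0.12) and rqh1 (-0.49 ± 0.11), with the same numbers adjusted over the list alone. Of 17 stress genes, hsp10 was higher (0.50 ± 0.12) and 2 were lower (1 and 1 adjusted over the list alone). Of 5 core histone genes, 0 passed by either count (limma), with 3 at an unadjusted p below 0.05, and values such as -0.85 ± 0.39 for htb1. Over all genes, 434 were higher and 438 lower. The split was 137 and 241 with arrays centred on the mode, 171 and 317 with normexp, and 84 and 112 with one spread. It was 138 and 92 without replicate 1 of rif1Δ and 129 and 95 without replicate 2.

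**Figure D2:**
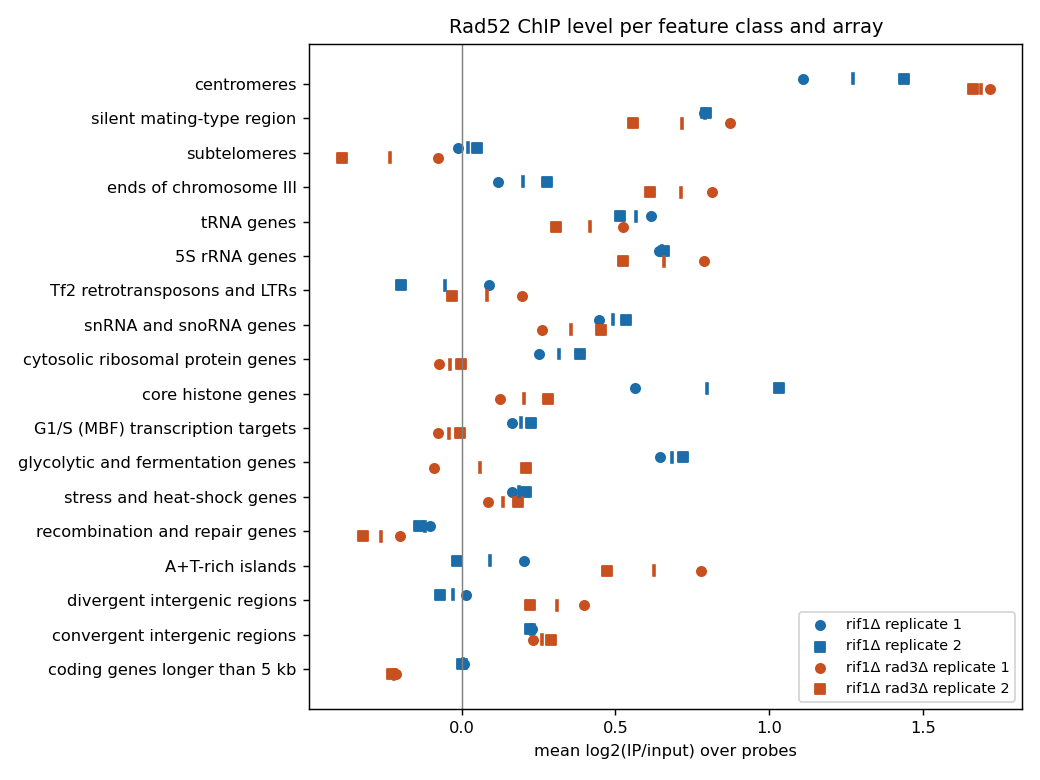
Mean log2 ChIP over input over the probes of each feature class (horizontal axis), for 18 classes (vertical axis), with a point for each array and a bar at each strain's mean. The silent mating-type region is drawn from limits that begin at mat1. Glycolytic genes lie at 0.65 and 0.72 on the rif1Δ arrays and at -0.090 and 0.21 on the rif1Δ rad3Δ arrays.

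The right end of chromosome III, from the probe at 2150187 to the last probe, was higher in rif1Δ rad3Δ, at 0.65 against 0.034 in rif1Δ. The difference was 0.61 ± 0.16 (SE, n = 2 arrays per strain) with a limma adjusted p of 0.0441, in a region chosen after its values were seen. It was 0.81 within the slide that held both strains. It no longer passed without replicate 1 of rif1Δ rad3Δ (0.40) or either rif1Δ array (0.63 and 0.59), with normexp (0.53), mode centring (0.54), one spread (0.48) or the A+T trend removed (0.56). Without this region, 2156 bins differed between the strains.

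**Figure D3:**
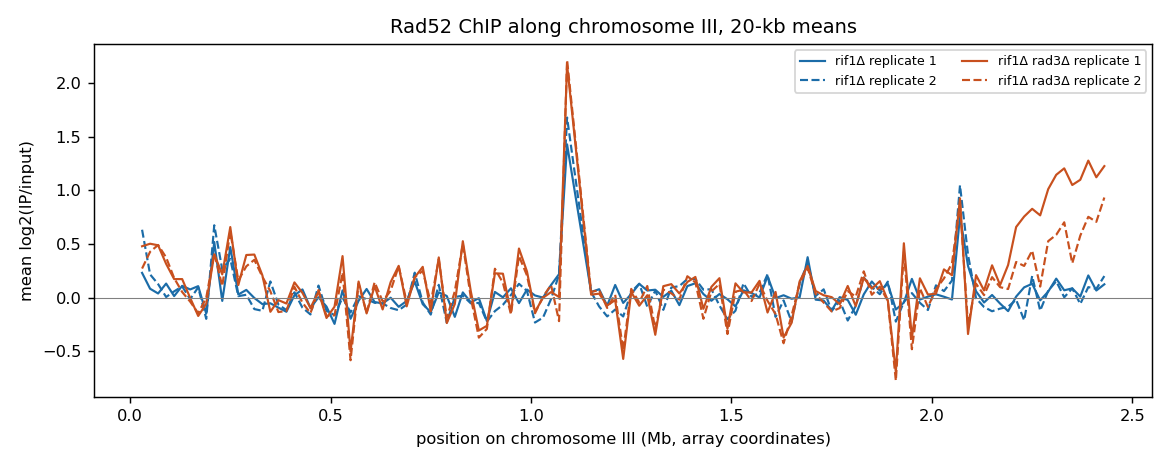
Mean log2 ChIP over input in 20-kb steps (vertical axis) along chromosome III in Mb (horizontal axis), with a line for each array. Both rif1Δ rad3Δ arrays rise toward the right end, where the mean from 2150187 on is 0.86 and 0.43, against 0.055 and 0.013 on the rif1Δ arrays.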

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

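Of the tests below, those of the input channel and of A+T content on chromosome III were set before their results were seen, and the others after. The bound of 5% of bins for the A+T test of the dense pattern was also set after its value was seen. The first test of a weaker ChIP was the difference at centromeres (0.42 ± 0.13, SE), and it was replaced by the one given here after scaling the arrays had turned that difference to -0.27. The strains differed by a direct test in 2221 bins, at ade6 (-0.65), leu1 (-0.60), the mat1 region (-0.80), the right end of chromosome III (0.61) and the centromere of chromosome III (0.61), which is what singled these out. Mitochondrial probes, which no comparison used, differed by -1.08 between the strains (log2 ChIP over input, rif1Δ rad3Δ minus rif1Δ).

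The dense pattern of rif1Δ rad3Δ is a first pattern to weigh. Once each array's trend on A+T content over 1 kb was removed, 11.9% of bins still differed, against 18.7% of the same bins before. That trend alone therefore does not account for all of the pattern, and other effects of base content were not tested. The same profile at a larger scale would give a correlation between strains near that of replicates, and the ratio was 0.519 (95% bootstrap interval 0.483 to 0.553). Intervals in this paragraph come from 1000 draws of 50-kb blocks of the genome, with the same 4 arrays in each draw. They hold no spread between arrays. An effect only of the slides of the replicate 2 arrays is argued against by the slope of the difference within slide 1 on that of those arrays. The slope was 0.741 (0.709 to 0.774). It also argues against an effect only of the Feature Extraction protocol that rif1Δ rad3Δ replicate 2 alone had. With arrays scaled to one spread 457 bins differed, so scale sets part of the count, and an effect of the loss of Rad3 stays open and untested.

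The rise at the right end of chromosome III is a second pattern. The input channel differed there by 0.046 ± 0.13 (SE) and the ChIP channel by 0.67 ± 0.35 (SE), so less DNA in the input does not account for the rise. It went from 0.61 ± 0.16 to 0.56 ± 0.16 (SE) with the A+T trend removed, where it no longer passed, and was 0.81 within slide 1. The arrays leave the explanation open.

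The lower levels at glycolytic genes in rif1Δ rad3Δ are the last pattern. A weaker ChIP would leave classes with one share of their rif1Δ level. However, the share kept at centromeres exceeded that at glycolytic genes by 1.24 ± 0.18 (SE). With arrays scaled to one spread the excess was 0.786 ± 0.126 (SE). Scaling changes both shares by roughly one factor, from 1.33 to 0.832 at centromeres and from 0.0877 to 0.0464 at glycolytic genes. The scaled value is therefore not a separate check. With the A+T trend removed the excess was 0.711 ± 0.201 (SE). In this last setting the margin as written, set by the SE, was met. The stricter margin used in the calculation was not, so the test is undecided there. Strongly transcribed genes can be enriched in a ChIP without the protein being there, and with a mean of 0.060 ± 0.090 (SE) in rif1Δ rad3Δ this cannot be told apart from a loss of Rad52, since neither transcription nor a ChIP without Rad52 was measured here. Mitochondrial DNA, which nuclear Rad52 should not bind, also changed, by -1.08. With the A+T trend removed the difference of the glycolytic class was -0.34, so part of the glycolytic difference may follow base content.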

How the results depend on the processing

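The mating-type region without mat1, the run without the right end of chromosome III and the run without the unnamed arm of chromosome I were added after seeing the data. The mating-type class stood at 0.77 in rif1Δ and 0.67 in rif1Δ rad3Δ without mat1, against 0.79 and 0.72 with it. It passed in limma in both strains either way, but not in camera with an estimated correlation (adjusted p 0.205 and 0.449, with mat1), and the part without mat1 holds 8 probes. Shares below are percent of bins tested, with 4.32% enriched in rif1Δ, 24.5% in rif1Δ rad3Δ and 18.4% different in the report.
With arrays scaled to one spread the shares were 7.85%, 15.7% and 3.79%, and 41.8% of enriched rif1Δ bins were shared. The scaling also turned the difference at the centromere of chromosome III to -0.26, at the bin at 1623000 on chromosome II to -0.27 and at the bin at 1097000 on chromosome III to -0.17. Single probes gave 1.89%, 15.8% and 1.73%. Bins of 5 kb gave 7.05% enriched in rif1Δ and 36.5% different, and bins of 50 kb 7.97% enriched in rif1Δ, with rif1Δ replicate correlations of 0.774 and 0.783. Normexp gave 16.2% enriched in rif1Δ rad3Δ and 11.2% different, centring on the mode 11.3% and removal of the A+T trend 11.9% different, and a 1.5-fold limit 12.7% enriched in rif1Δ rad3Δ. The cause was not tested.
Leaving out each array gave 1.73% to 5.34% enriched in rif1Δ, 8.62% to 10.9% different, 40.8% to 73.1% shared, 7 to 11 classes above 0 in rif1Δ and 0 to 3 classes different, with fewer samples and the lone array assumed to vary like the others. Of the class differences, 11 passed with normexp, 6 each with loess, A+T removal and the replicate block, 5 with class medians, 1 each with mode centring and scaling, and 11 with camera's preset correlation. Camera with an estimated correlation, which rests on 2 residual degrees of freedom, called 0 classes in rif1Δ, in rif1Δ rad3Δ and between them. Deviations of same-numbered arrays correlated at 0.329, and with only 2 pairs this does not pair them. The replicate block gave 11.7%, 30.9% and 37.9%, with 6 classes different. Slide as a block left no residual degrees of freedom, so only values within slide 1 are given, and its random form could not be fitted. Signals of rif1 and rad3 near background limit what can be read there.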

Other observations

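Mitochondrial DNA, which nuclear Rad52 should not bind, was near the median of nuclear probes in the rif1Δ ChIP and far below that median in rif1Δ rad3Δ. Median log2 ChIP over input of its 66 probes was -0.20 ± 0.0064 in rif1Δ and -1.28 ± 0.082 in rif1Δ rad3Δ (SD, n = 2 each). No test was run on this value.

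One probe inside rad52, at 1100087 to 1100146 on chromosome I, stood at 3.95 and 1.53 on the rif1Δ arrays and 2.15 and 0.56 on the rif1Δ rad3Δ arrays. The next probe, at 1100286, was at 0.34, 0.13, 0.18 and 0.0030. It was noticed after the values were seen, and the rad52 mean in the report includes it.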
